A study of Mus musculus with 5 samples.

How the data were processed

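Poly-A RNA from sorted aortic macrophages was turned into cDNA with the SMARTer Ultra Low kit, which is made for few cells, amplified over 12 PCR cycles with indexed primers and sequenced as single reads of 50 bases on a HiSeq-3000, per the labels' protocols. The deposited files held 1 table per library with 41388 Ensembl gene IDs, each with chromosome, start, end, strand, length, read count, CPM and RPKM, per the file headers. The genome build was GRCm38, and the submitters' processing notes name STAR 2.0.4b, Subread and featureCounts 1.4.5; they give no roles, annotation release or strand setting. The deposited count column held whole reads per gene. The CPM and RPKM columns that the authors deposited equalled those computed from the deposited counts, with 0 mismatches at a tolerance of 1e-06, so these carry no normalization beyond library size and gene length, and all tests used the counts. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart.

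Gene symbols came from a reference table of Ensembl IDs and were found for 40254 of 41388 IDs; the 1134 IDs without one took 0.148 to 0.228% of the reads, and 8 symbols were shared by more than 1 ID. Coordinates are those of the files. Of the IDs, 97.5% were also in GENCODE M21. The 5 libraries totalled 3941381 to 20806925 reads. A floor of 3 reads corresponds to 0.761 CPM in the smallest library and 0.144 CPM in the largest. Intervals and floors are at 95% and cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

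Genes were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3 after filterByExpr by group, which uses a minimum count of 10 and a minimum total of 15, with TMM factors over all 5 libraries and no covariates. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. The standard error of a log2 difference is its size divided by the square root of the F statistic. Normalised CPM used TMM-adjusted library sizes. Low-read ratios used the reads of a group over its summed TMM-adjusted library sizes, with exact Poisson intervals for the group with few reads. Gene lists were tested with camera of limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and adjustment over lists with at least 5 tested genes, and again with the correlation estimated for each list and with fry, which asks only whether the genes of a list move one way on balance.

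The 30 gene lists, the test, the named genes and most of the alternatives were fixed before the data were examined. Named genes were Apoe and the sort markers; the 12 largest called changes in each direction with an average log2 CPM of at least 4, a symbol that is not a predicted-gene or clone name, and group ranges that do not overlap; up to 2 called members per direction of each list; the most abundant member of each list of other cell types with no call, except that no value is given for single red cell markers; and Xist and Ddx3y. List members named beyond these, such as Trem2, Ccl8 and Kdr, were chosen after their values were seen. The lists cover LYVE1-type, core, lipid-associated and alternatively activated macrophages, MHC class I and II, inflammatory and interferon genes, cholesterol efflux, sterol synthesis, lysosome, matrix proteases, cell cycle, glycolysis, oxidative phosphorylation, unfolded protein response, dissociation, monocyte, dendritic, endothelial, smooth muscle, fibroblast, T and NK, B cell, neutrophil, mast, adipocyte and red cell markers, and mitochondrial and ribosomal genes.

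The gene test was tested on simulated counts drawn from the means and sizes of these libraries, with 12603 genes tested. It recovered 2% of 50 genes changed 4-fold, 42% at 16-fold, 54% at 64-fold and 84% at 256-fold, and 2 of its 93 calls were false. Camera called 5 of 5 changed lists and 0 of 22 unchanged ones. The simulated genes were drawn independently of each other and with the same spread in both groups. These rates therefore do not cover lists of correlated genes or the unequal spread of the real groups. Alternatives were other scalings, DESeq2 1.42.0, limma voom, a robust fit, other filters, a minimum 2-fold change with glmTreat, counts thinned to the smallest library, mitochondrial genes left out, the replicate number as a block, and each library left out in turn. Where intima was left with 1 library, that library was assumed to vary as the adventitia libraries do. Tables were joined with Python 3.11.15 and pandas 2.3.3, intervals came from scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.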

Results

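RNA sequencing libraries were made from macrophages sorted from the inner and outer layers of the mouse aorta. The 3 adventitia libraries came from Apoe-knockout mice given a high-fat diet for 28 weeks, with 6 mice named for the group, and their cells were sorted from the outer layer of the whole aorta as live CD64-positive cells. The 2 intima libraries came from C57BL/6 mice, each from 5 pooled animals, and their cells were sorted from the thoracic aorta after the outer layer had been taken off, as live cells positive for CD64, CD11c and MHC class II. The adventitia libraries held 3941381, 10076142 and 10054377 counted reads and the intima libraries 14970204 and 20806925. Tissue layer, genotype, aortic segment and sort gate all differed together between the groups, and the labels give a diet for the adventitia mice only, so a difference in the data belongs to their sum. The labels do not say whether the 6 knockout mice were divided among the adventitia libraries or sampled repeatedly, so p-values measure the spread between these libraries, part of which may be technical.

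Apoe, which encodes the lipid transport protein apolipoprotein E and is the gene disrupted in the adventitia donors, was high in the intima libraries and low in the knockout-derived adventitia libraries. Its TMM-normalised level was 18.2, 18.1 and 10.9 CPM (reads of a gene scaled to a common library total) in the adventitia libraries and 5563 and 4409 CPM in the intima libraries. The gene (ENSMUSG00000002985) lies on chromosome 7 from 19696109 to 19699166 in GRCm38. Its log2 difference, intima minus adventitia as everywhere below, was 8.31 (SE 0.54, n = 3 and 2, adjusted p = 8.33e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The counts are per gene and do not show which part of the transcript the remaining adventitia reads came from. Apoc4, another apolipoprotein gene of the same cluster on chromosome 7 (19678094 to 19681416), went the other way. It was at 33.5, 25.7 and 40.7 CPM in the adventitia and had no read in either intima library (adjusted p = 0.0280 in edgeR). Against a floor of 3 reads over the group it was at least 362-fold lower there, a bound that covers counting error only. With the intima libraries thinned to the smallest library, 14.2% of genes at 10 CPM or more in one were under 0.5 CPM in the other. The Apoc4 call was lost without any 1 of the adventitia replicates, with edgeR adjusted p-values of 0.215, 0.0743 and 0.140 without replicates 1, 2 and 3.

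The sort markers were measured in both groups. Fcgr1, which encodes CD64 and was gated in both sorts, was at 210 ± 97.0 CPM in the adventitia (SD, n = 3) and 162 ± 23.6 CPM in the intima (SD, n = 2), and the log2 difference of -0.37 did not pass the test (SE 0.52, adjusted p = 0.739 in edgeR). Itgax, which encodes CD11c and was gated only in the intima sort, was at 73.4 and 274 CPM in the intima against 16.8 to 33.8 CPM in the adventitia, yet its log2 difference of 2.74 missed the threshold (SE 0.65, adjusted p = 0.0868 in edgeR). The MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1 had log2 differences of -0.14, 1.01 and 0.78, with adjusted p-values of 0.929, 0.240 and 0.367 in edgeR. Xist, the RNA of the inactive X chromosome, was at no more than 1.31 CPM in any library, while the Y-linked gene Ddx3y was at 110 to 245 CPM.

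**Figure D1:**
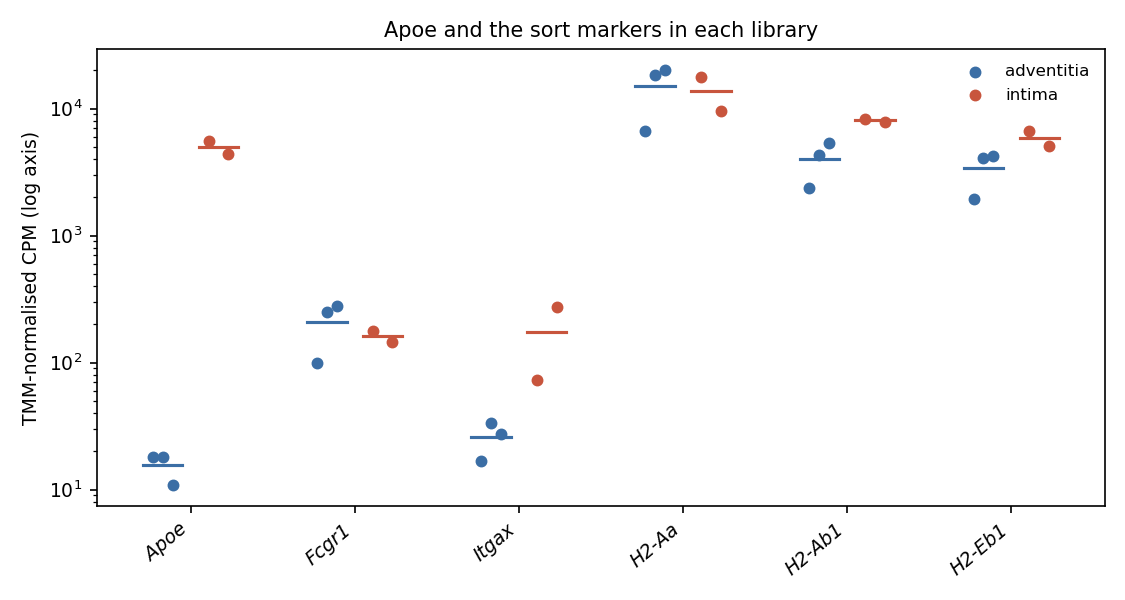
TMM-normalised CPM (log axis) of Apoe and 5 sort marker genes; each point is a library, blue for adventitia (n = 3) and red for intima (n = 2), and short lines are group means. Apoe lay at 10.9 to 18.2 CPM in the adventitia and at 4409 and 5563 CPM in the intima, while the Fcgr1 points of the groups overlapped.

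The smooth muscle marker Tagln was among the 12 largest called increases and the fibroblast marker Lum among the 12 largest decreases. Both are given below with markers of other cell types. Which cell type supplied the reads of the called genes was not tested. Called genes with large increases in the intima libraries included Cytl1, Clu, Efna5 and H2-M2. Cytl1, a small secreted cytokine-like protein, was at 851 ± 145 CPM in the intima (SD, n = 2) and 1.84 ± 0.938 CPM in the adventitia (SD, n = 3). Clu, the extracellular chaperone clusterin, was at 832 ± 551 against 2.09 ± 0.866 CPM. Efna5, a membrane-bound ephrin ligand, was at 341 against 0.992 CPM, and H2-M2, a non-classical MHC class I gene, at 265 against 0.946 CPM. The log2 differences of these 4 genes were 8.89 (SE 0.63), 8.68 (SE 0.66), 8.46 (SE 0.69) and 8.10 (SE 0.63), and their adjusted p-values in edgeR lay between 1.05e-04 and 1.85e-04.

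Other large increases in the intima included Cav1, the coat protein of caveolae, at 325 against 0.894 CPM (log2 difference 8.73, SE 0.98). Bmp6, a bone morphogenetic protein, rose by 8.17 (SE 1.17), Adamdec1, a secreted metalloprotease, by 8.13 (SE 1.14) and Pdgfd, a platelet-derived growth factor, by 7.87 (SE 1.04) on the log2 scale. Ifnb1, which encodes interferon beta, was at 22.3 and 81.7 CPM in the intima against a single read in the adventitia libraries, a ratio of 1303 with a 95% counting interval of 234 to 51463. Myct1 was at 39.7 and 63.5 CPM against 3 reads in the adventitia, a ratio of 431 with an interval of 148 to 2092. All 6 genes passed the edgeR test, with adjusted p-values from 0.00220 for Cav1 to 0.0178 for Ifnb1. Without adventitia replicate 1 the calls of Bmp6, Adamdec1, Pdgfd, Ifnb1 and Myct1 were lost, with adjusted p from 0.118 to 0.215 in edgeR; those of Ifnb1 and Myct1 were also lost without adventitia replicate 2 (0.0696 and 0.0586) and without adventitia replicate 3 (0.0977 and 0.115).

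Genes higher in the adventitia included Cd209a, a C-type lectin of the DC-SIGN family, at 269 ± 107 CPM (SD, n = 3) against 0.476 ± 0.103 CPM in the intima (SD, n = 2), a log2 difference of -9.13 (SE 0.76, adjusted p = 1.92e-04 in edgeR). Cxcl13, a chemokine that attracts B cells, was at 362 ± 254 against 0.157 CPM, with a log2 difference of -11.29 (SE 1.32, adjusted p = 0.00287 in edgeR). Vsig4, a complement receptor of resident macrophages, had a log2 difference of -9.48 (SE 1.18, adjusted p = 0.00374 in edgeR). Mmp3, the protease stromelysin 1, was at 47.7, 43.0 and 329 CPM in the adventitia and 0.235 and 0.0504 CPM in the intima (adjusted p = 0.00845 in edgeR). Plac8, Slfn1, Igfbp5, Ogn, Fpr2 and Kmo had adventitia means of 54.3, 46.0, 39.6, 40.7, 37.2 and 39.4 CPM and 1 to 3 reads in the intima libraries together. The ratios of these 6 genes ran from 428 for Kmo, with a 95% counting interval of 146 to 2076, to 1771 for Plac8, with an interval of 318 to 69938. These intervals cover counting error only and leave out the disagreement between the intima libraries given above. Without adventitia replicate 1 the calls of all genes of this group but Cd209a were lost, with edgeR adjusted p from 0.118 to 0.242; without adventitia replicate 3 those of Mmp3, Plac8, Slfn1, Igfbp5, Ogn, Fpr2 and Kmo (0.100 to 0.163), without adventitia replicate 2 those of Fpr2 and Kmo (0.125 and 0.0580), and without intima replicate 2 those of Mmp3, Ogn and Kmo (0.0522, 0.0522 and 0.0613) were lost.

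The edgeR test covered 13408 genes and called 90, of which 70 were higher and 20 lower in the intima (77.8% higher). The split was 46 higher and 29 lower with upper-quartile scaling (61.3%) and 59 and 34 with library size alone (63.4%). It turned to 488 higher and 692 lower with DESeq2 on the same 13408 genes (41.4%), a setting chosen after seeing the data, and to 501 and 1658 with DESeq2 and its own filter on the 31645 genes with a read (23.2%), on which edgeR called 312 and 74 (80.8%). It was 214 and 625 with limma voom (25.5%) and 135 and 261 with a filter of 1 CPM in every library of a group (34.1%). The median log2 difference of all tested genes was 0.14 with TMM, -0.35 with upper-quartile scaling and -0.09 with library size alone. The CPM ranges of the groups did not overlap for 5486 of the 13408 tested genes (40.9%), where chance gives 20% in 3 against 2 libraries, and the 90 called genes were all among them. The 2 intima libraries differed from each other more than the adventitia libraries did, with a common biological coefficient of variation of 1.28 against 0.703. The number of calls rested on single libraries: it was 10 without adventitia replicate 1, 52 without adventitia replicate 2, 46 without adventitia replicate 3, 389 without intima replicate 1 and 136 without intima replicate 2. Leaving out an adventitia library also leaves fewer libraries for the test, and lost power was not told apart from the influence of that library. With 10 ways to split 5 libraries into 3 and 2, an exact two-sided permutation test of a single gene cannot give a p below 0.1.

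**Figure D2:**
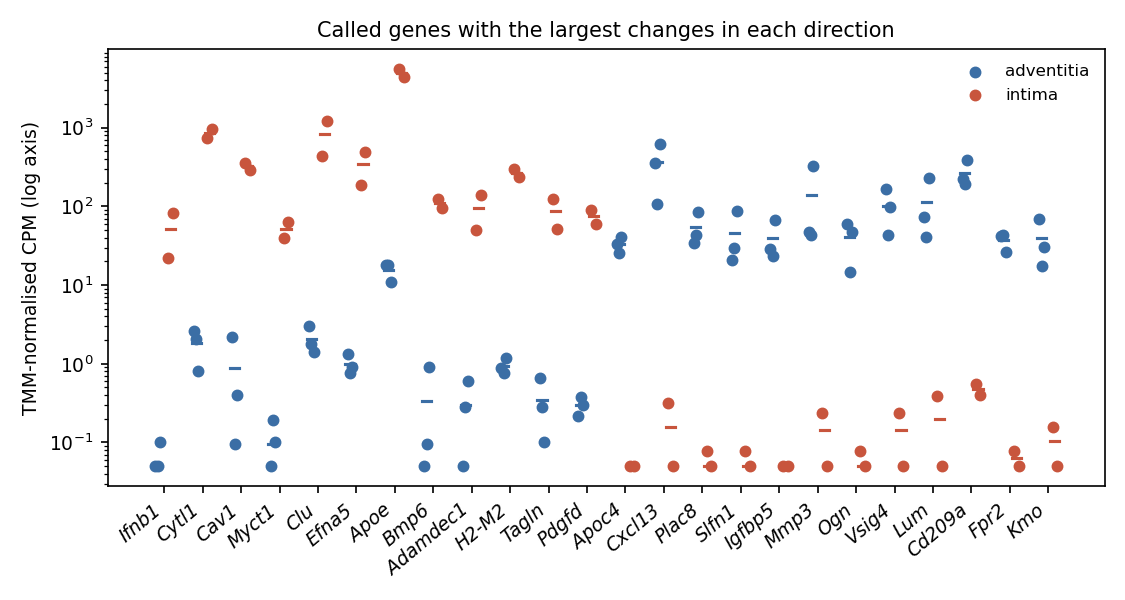
TMM-normalised CPM (log axis) of the 24 called genes with the largest increases (left) and decreases (right) in the intima; each point is a library, blue for adventitia (n = 3) and red for intima (n = 2), short lines are group means, and values under 0.05 CPM are drawn at 0.05. The genes were chosen among those whose groups do not overlap, and Apoc4 had no read in the intima.

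Gene lists fixed before the data were examined were tested as sets with camera, which asks whether the genes of a list differ more in one direction than the other genes, and 10 of 27 lists passed at the preset inter-gene correlation of 0.01, 6 toward the intima and 4 toward the adventitia. None passed when the correlation was estimated from the 5 libraries. The endothelial, smooth muscle and alternatively activated lists were lost too, although their estimated correlations of -0.062, -0.031 and 0.0041 lay below the preset. A higher correlation thus does not account for the loss of these lists. With an estimated correlation camera also uses the 3 residual degrees of freedom of the 5 libraries. That setting therefore differs from the preset in more than the correlation. Fry called 4 of the 10 and not those of LYVE1-type, MHC class II, lipid-associated, lysosomal, cell cycle and fibroblast genes (adjusted p = 0.112, 0.190, 0.0568, 0.149, 0.307 and 0.0743). Genes of lipid-associated macrophages were higher in the intima as a set: 3 of 16 tested members rose, none fell and 13 did not pass, with 6 higher when adjusted over the list alone. Mmp12, macrophage elastase, was at 2250 and 3866 CPM in the intima against 81.4 to 187 CPM in the adventitia (log2 difference 4.69, SE 0.53, adjusted p = 0.00220 in edgeR). Cd9, a tetraspanin, rose by 2.74 (SE 0.45) and Lgals3, galectin 3, by 2.16 (SE 0.42) on the log2 scale, with adjusted p-values of 0.0192 and 0.0482 in edgeR. Without adventitia replicate 1 the adjusted p was 0.124 for Mmp12 and 0.215 for Cd9, and without adventitia replicate 2 it was 0.125 for Cd9. That of Lgals3 was 0.215, 0.145 and 0.121 in edgeR without adventitia replicates 1, 2 and 3 and 0.0585 without intima replicate 2. Trem2, Spp1 and Cd36, which name such cells in other settings, had log2 differences of 0.60, -0.04 and 0.38 and did not pass. The list's median was 1.17, with a camera adjusted p of 6.58e-05 at the preset correlation and adjusted p = 0.428 with an estimated correlation. Lysosomal genes had a median log2 difference of 0.66 over 20 tested members, none of which passed over all genes and 5 of which were higher when adjusted over the list alone, among them Acp5 at 3.26. That list had a camera adjusted p of 6.85e-04, adjusted p = 0.428 with an estimated correlation, and adjusted p = 0.101 with only genes at 1 CPM in all 5 libraries.

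MHC class II antigen presentation, whose protein was part of the intima gate, had a median log2 difference of 1.46 over 13 tested members, with 0 called over all genes and 0 when adjusted over the list alone. Cd74, the class II invariant chain, was at 88128 and 61307 CPM in the intima and 8673 to 38778 CPM in the adventitia, and Ciita, the class II transactivator, had a log2 difference of 2.99 (SE 0.87) that did not pass. The camera adjusted p of the list was 3.13e-04, and adjusted p = 0.428 with an estimated correlation. Cell cycle genes had a median of 1.74 over 20 tested members, with 0 called over all genes and 3 higher when adjusted over the list alone. Mki67 was at 56.9 and 165 CPM in the intima against 26.0 to 42.8 CPM in the adventitia, while Mcm5 was at 3.14 CPM in intima replicate 1 and 233 CPM in intima replicate 2. The list had a camera adjusted p of 4.31e-04, adjusted p = 0.572 with an estimated correlation, and adjusted p = 0.192 without intima replicate 2.

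Genes of LYVE1-type resident macrophages, a population of vessel surroundings, were lower in the intima as a set, with a median log2 difference of -1.21 over 20 tested members. No member passed over all genes and 5 were lower when adjusted over the list alone. Ccl8, a monocyte-attracting chemokine, was at 5078 to 9646 CPM in the adventitia and 311 and 12.1 CPM in the intima (log2 difference -5.62, SE 1.18, adjusted p = 0.0657 in edgeR). Folr2, the folate receptor beta, had a log2 difference of -2.20 (SE 0.52) and Lyve1 one of -1.16 (SE 0.61), neither past the threshold. The camera adjusted p was 3.99e-05, and adjusted p = 0.428 with an estimated correlation. Genes of alternatively activated macrophages had a median of -2.40 over 9 tested members, also with Ccl17, which had no read in the intima, set at its bound. None of them passed over all genes and 3 were lower when adjusted over the list alone. That list had a camera adjusted p of 0.00244, adjusted p = 0.428 with an estimated correlation, and adjusted p = 0.160 without intima replicate 2, in which Retnla was at 30.7 CPM against 2379 CPM in intima replicate 1.

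The 16 genes shared by most tissue macrophages had a median log2 difference of -0.26, with Csf1r at 0.21, Adgre1 at 1.08 and Itgam at -1.34, and camera did not call the list (adjusted p = 0.976). Adjusted over the list alone 1 member was higher, Cx3cr1, with a log2 difference of 2.32 (SE 0.51, adjusted p = 0.0130 in edgeR over the list and 0.0814 over all genes). Among 12 tested monocyte markers Plac8 fell, as given above, and Ace, the angiotensin-converting enzyme, rose by 5.34 on the log2 scale (SE 0.76, adjusted p = 0.00797 in edgeR), with 2 higher and 3 lower when adjusted over the list alone. Mmp13, collagenase 3, was the only called member of 15 tested matrix protease genes, at 960 and 875 CPM against 2.84 to 23.3 CPM (log2 difference 6.28, SE 0.75, adjusted p = 0.00314 in edgeR). Uqcrc1, a subunit of respiratory complex III, was the only called member of 20 tested oxidative phosphorylation genes, with a log2 difference of 3.49 (SE 0.53, adjusted p = 0.0113 in edgeR), and 3 of that list were higher when adjusted over the list alone. Camera did not call the lists of matrix proteases, oxidative phosphorylation or monocytes (adjusted p = 0.495, 0.170 and 0.755). It also did not call inflammatory genes (adjusted p = 0.307), interferon-stimulated genes (0.175), MHC class I (0.492), cholesterol efflux (0.310), sterol synthesis (0.775), glycolysis and hypoxia (0.225) or the unfolded protein response (0.775), none of which had a called member. Fry gave sterol synthesis and the unfolded protein response the opposite sign to their medians of 0.24 and 0.35. Without adventitia replicate 1 the edgeR adjusted p was 0.124 for Ace, 0.0501 for Mmp13 and 0.166 for Uqcrc1, and without adventitia replicate 3 it was 0.0651 for Uqcrc1. Adjusted over the list alone, 3 inflammatory genes were lower and 2 glycolysis genes higher. Ccl2, a chemokine that attracts monocytes, was at 4165 to 5054 CPM in the adventitia and 1273 and 733 CPM in the intima, without passing (adjusted p = 0.0783 in edgeR).

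Markers of other cell types moved with these groups. Endothelial markers were higher in the intima: 4 of 12 tested members rose, none fell, and 8 were higher and 1 lower when adjusted over the list alone. Pecam1, an adhesion protein of endothelial junctions, rose by 6.64 (SE 0.75), Ptprb, an endothelial phosphatase, by 6.98 (SE 0.66), Esam by 6.69 (SE 1.10) and Vwf, von Willebrand factor, by 3.23 (SE 0.59) on the log2 scale, with adjusted p-values from 6.14e-04 for Ptprb to 0.0344 for Vwf in edgeR. The list's CPM summed to 1053 ± 29.9 in the intima (SD, n = 2) and 44.2 ± 7.04 in the adventitia (SD, n = 3). Kdr, a VEGF receptor, was at 0.235 and 0.0504 CPM in the intima and 1.09 to 1.81 CPM in the adventitia. The list had a median of 4.11, a camera adjusted p of 6.58e-05, and adjusted p = 0.428 with an estimated correlation. Of 8 tested smooth muscle markers Tagln, the actin-binding protein transgelin, rose by 8.09 on the log2 scale (SE 1.10, adjusted p = 0.00697 in edgeR), and 3 were higher when adjusted over the list alone. Acta2, smooth muscle actin, was at 171 and 24.6 CPM in the intima, and Myh11, smooth muscle myosin, at 0.470 and 0 CPM. The smooth muscle list had a median of 2.84, a camera adjusted p of 0.0183, adjusted p = 0.428 with an estimated correlation, adjusted p = 0.0753 without intima replicate 2, and adjusted p = 0.171 without its top gene. Without adventitia replicate 1 the edgeR adjusted p was 0.118 for Pecam1 and for Tagln. Without adventitia replicates 1, 2 and 3 it was 0.165, 0.0721 and 0.101 for Esam and 0.215, 0.0743 and 0.140 for Vwf; it was also 0.0629 for Esam without intima replicate 2 and 0.0650 for Vwf without intima replicate 1.

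Of 12 tested fibroblast markers Lum, the matrix protein lumican, fell: it was at 74.2, 41.4 and 228 CPM in the adventitia and 0.392 and 0 CPM in the intima (log2 difference -9.27, SE 1.47, adjusted p = 0.0148 in edgeR), and 4 were lower when adjusted over the list alone. The fibroblast median was -1.07, with a camera adjusted p of 0.0166, adjusted p = 0.428 with an estimated correlation, and adjusted p = 0.267 without intima replicate 1. The fibroblast call was also lost in camera with no filter beyond 1 read (adjusted p = 0.0807), with the replicate block (0.121), with 1 CPM in all 5 libraries (0.109) and without the top gene (0.0769). The Lum call was lost without adventitia replicate 1 (adjusted p = 0.174 in edgeR) and without adventitia replicate 3 (0.139). Of 12 tested dendritic cell markers Cd209a and Kmo fell, and 1 was higher and 6 lower when adjusted over the list alone. The dendritic median was -4.39, and -4.34 with Xcr1, which had no intima read, at its bound. That list had a camera adjusted p of 0.0166, adjusted p = 0.428 with an estimated correlation, adjusted p = 0.533 without intima replicate 1 and 0.0994 without intima replicate 2. The dendritic call was also lost in camera with no filter beyond 1 read (adjusted p = 0.191), after thinning to the smallest library (0.0594) and without the top gene (0.0781). No T and NK cell, B cell or neutrophil marker passed, and camera did not call these lists (adjusted p = 0.755, 0.775 and 0.102), although 3 neutrophil genes were lower when adjusted over the list alone. B cell genes differed in sign between the median of 0.59 and the mean of -0.76, and fry gave them the opposite direction to camera. The most abundant members were Il7r at 18.6 CPM in the adventitia and 20.3 CPM in the intima, Ighm, the immunoglobulin M heavy chain, at 440 and 1002 CPM, and Csf3r at 18.7 and 33.9 CPM. With 3 tested members each, the mast cell and adipocyte lists were not tested as sets; 1 of each was lower when adjusted over the list alone, and their most abundant genes, Hdc and Car3, were at 6.62 and 4.21 CPM in the adventitia and 9.59 and 0.297 CPM in the intima. No red cell marker had enough reads for the test.

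**Figure D3:**
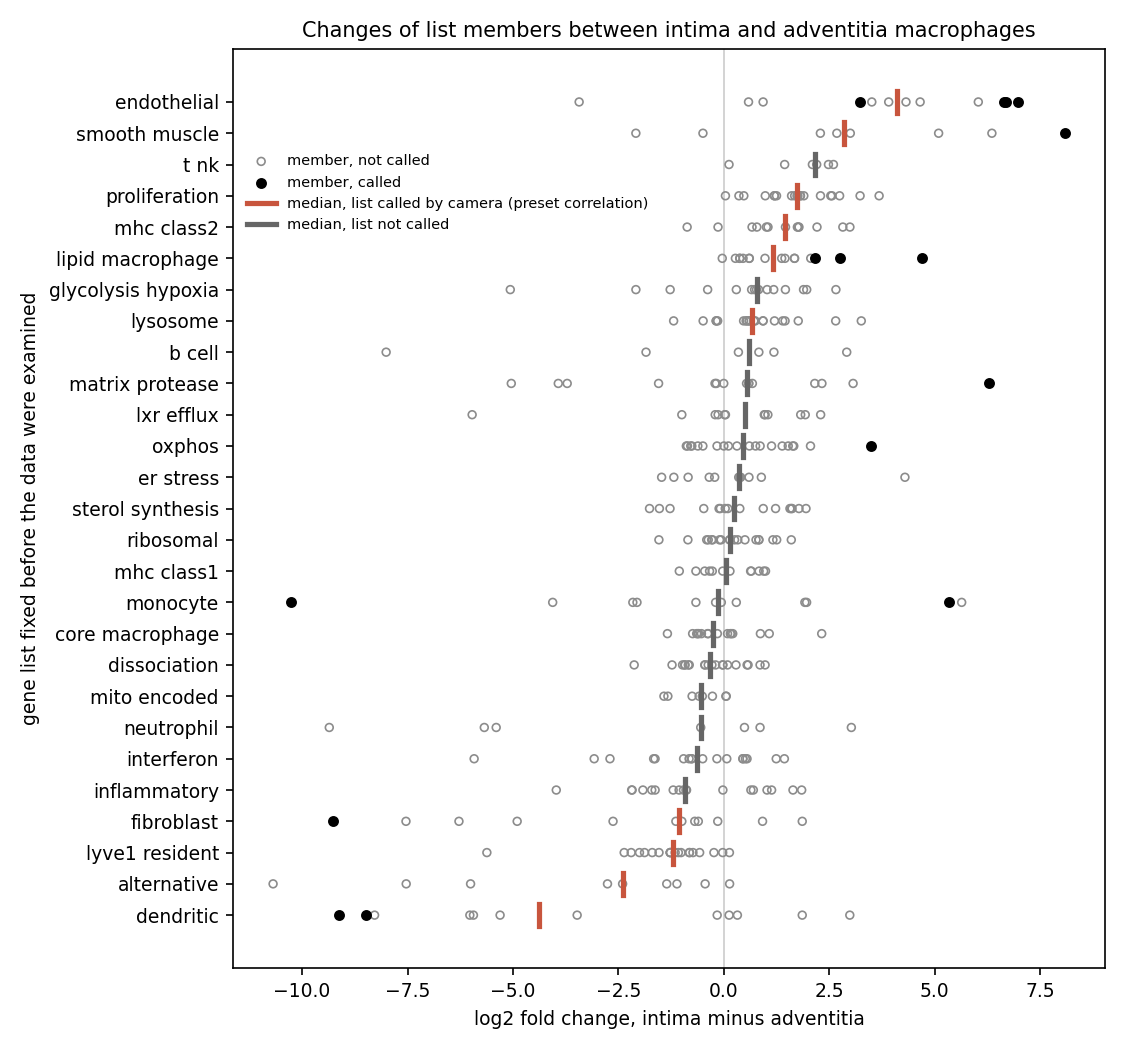
Log2 fold changes, intima minus adventitia (horizontal axis), of the tested members of 27 gene lists (rows); filled points passed the edgeR test, open points did not, and vertical bars are list medians, red where camera called the list at its preset correlation. Endothelial markers had the highest median (4.11) and dendritic cell markers the lowest (-4.39).

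Signs of RNA quality and the number of genes with a read were measured in each library. Immediate early and heat shock genes, which tissue dissociation raises, had a median log2 difference of -0.33 and were not called by camera (adjusted p = 0.532), with Fos at 0.29 and Dusp1 at -0.82. Mitochondrially encoded and ribosomal protein genes had medians of -0.55 and 0.14 and were not called either (adjusted p = 0.169 and 0.285). Mitochondrial genes took 6.15, 3.96 and 3.27% of the adventitia reads and 2.30 and 1.38% of the intima reads. The intima libraries had reads on 17489 and 16374 genes and the adventitia libraries on 23289, 25212 and 25738; at an equal 3941381 reads the numbers were 13220 and 12856 against 23289, 21012 and 21286. Gapdh was listed at 1.02 to 5.69 CPM in every library and mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8 at 0, and levels of genes with near-identical copies elsewhere in the genome are uncertain in these files.

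**Figure D4:**
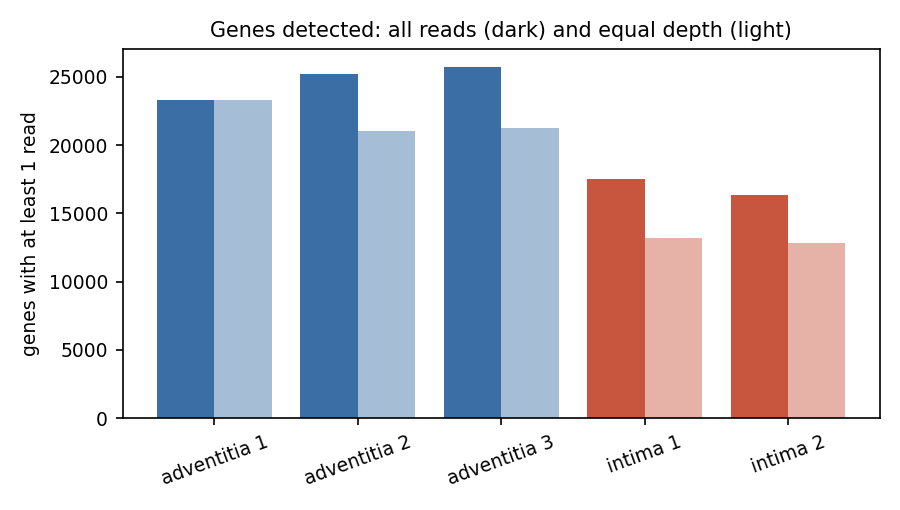
Number of genes with at least 1 read in each library, with all reads (dark bars) and after random thinning of every library to 3941381 reads (light bars), blue for adventitia and red for intima. At equal depth the intima libraries had 13220 and 12856 genes and the adventitia libraries 21012 or more.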

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

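Voom with a weight per group and DESeq2 on the genes of the edgeR test were chosen after seeing the data. So were the filter of 1 CPM in all 5 libraries and the count of calls without overlap. That count stayed at 90, but it only filters the calls of the main test and is no test of its own. The other alternatives were planned. All 90 called genes kept their direction wherever they were tested, and no named gene or list with a call changed direction; fry gave the sterol synthesis, unfolded protein response and B cell lists, which had no call, the opposite direction to camera. Across the alternatives 772 tests of named genes kept their side of the threshold, 49 lost the call and 6 gained one; for lists the numbers were 411, 31 and 29. Voom with group weights ended the calls of Cxcl13, Mmp3, Lum and Cd209a, and glmTreat that of Cd9. Apoe, Cytl1, Clu, Efna5, Cav1, H2-M2 and Ptprb kept their calls in every alternative in which they were tested, which for Cytl1, Efna5, Cav1 and H2-M2 leaves out the filter of 1 CPM in all 5 libraries, Apoe with log2 differences of 7.82 to 8.56 and adjusted p up to 0.0165.

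The number of calls (90, of which 70 higher and 20 lower in the intima) was 2159 with DESeq2 and its own filter on the 31645 genes with a read (501 and 1658), 1180 with DESeq2 on the 13408 genes of the edgeR test (488 and 692), 839 with limma voom (214 and 625), 192 with voom and group weights (127 and 65), 386 with edgeR and no filter beyond 1 read, also on 31645 genes (312 and 74), 396 with 1 CPM in every library of a group (135 and 261) and 183 with the replicate block (133 and 50). Most calls of DESeq2, voom without group weights and the filter of 1 CPM in every library of a group were thus lower in the intima. Calls higher were 46 with upper-quartile factors; calls lower were 34 with library size only, 33 after thinning and 43 with 1 CPM in all 5 libraries. Leaving out 1 library gave 10 to 389 calls, 9 to 229 higher and 1 to 160 lower. The cause of these differences was not tested. The deviations of same-numbered libraries had correlations of 0.035 and -0.017. With 2 intima libraries the deviations of one mirror those of the other, so these values cannot decide whether the numbers pair libraries. The block has no known basis.

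Among Apoe and the sort markers 1 gene was called; it was 2 with DESeq2 on either gene set, 3 with no filter beyond 1 read, and 1 to 2 on leaving out a library. The number of called lists (10) was 0 with the estimated correlation, 4 with fry and 16 with no filter beyond 1 read. The intima mean of H2-Ab1 was 8073 CPM, and 7282 CPM with library size only. Set tests were not run with DESeq2 or glmTreat, which give none. Of simulated 4-fold changes 2% were recovered.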

Other observations

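The genes named in the first 2 paragraphs were chosen after their values were seen. Called genes outside the named sets included Edn1, Gja5, Bmp4, Ocstamp and Dnase1l3. Edn1, the vasoconstrictor endothelin 1, was at 191 and 150 CPM in the intima against 0.381 to 3.80 CPM in the adventitia (log2 difference 6.47, adjusted p = 0.00742 in edgeR). Gja5, the gap junction protein connexin 40, Bmp4, Emcn, Ecscr and Clec14a rose by 7.75, 6.62, 7.21, 7.44 and 6.06 on the log2 scale. Whether macrophages or cells of the vessel wall supplied the reads of these genes and of Edn1 was not tested. Ocstamp, a membrane protein needed for fusion of osteoclast precursors, was at 64.2 and 338 CPM against 1.20 to 2.41 CPM (log2 difference 6.79, adjusted p = 0.00350 in edgeR). Dnase1l3, a secreted nuclease of macrophages and dendritic cells, was at 1782 and 2850 CPM against 8.53 to 43.3 CPM, a log2 difference of 6.31. Without adventitia replicate 1 all of these calls but that of Dnase1l3 were lost, with edgeR adjusted p from 0.0501 for Emcn to 0.215 for Gja5. Those of Gja5 and Clec14a were also lost without adventitia replicate 2 (0.124 and 0.0566) and adventitia replicate 3 (0.0638 and 0.121), that of Gja5 without intima replicate 2 (0.0534) and that of Clec14a without intima replicate 1 (0.0635).

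Among the 20 genes called lower in the intima were the complement components C3 and C4b, with log2 differences of -4.39 and -3.36 (adjusted p = 0.0393 and 0.0104 in edgeR). Ccl12, a monocyte chemokine, was at 2518 to 3373 CPM in the adventitia and 361 and 108 CPM in the intima, a log2 difference of -3.64. Saa3, an acute phase protein, Mir155hg, the host transcript of microRNA 155, and Nr4a3, an immediate early nuclear receptor, had log2 differences of -6.69, -5.31 and -6.99. All 6 of these calls were lost without adventitia replicate 1, with edgeR adjusted p from 0.124 for C4b to 0.242 for Saa3. Without adventitia replicate 2 those of C3, Ccl12, Mir155hg and Nr4a3 (0.151, 0.0589, 0.0941 and 0.175), without adventitia replicate 3 all but that of C4b (0.0629 to 0.140) and without intima replicate 2 that of C3 (0.0703) were lost.

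In the paragraphs that follow, the tests of wall cells and of macrophage share were chosen after the marker values were seen, and the bounds used for exchanged reads and for genes near Apoe were changed and the ratio to Apoe reads was added after their results were seen. The first pattern is the rise of endothelial and smooth muscle markers. A lower share of macrophages was predicted to raise fibroblast markers too. Their median log2 difference was -1.07, with quartiles below those of the endothelial markers. The intima cells were sorted after the outer layer had been taken off, which alone could lower fibroblast markers. This result therefore cannot decide on the share of macrophages. Of the 20 tested markers of both lists, 11 lay above every adventitia library in both intima libraries, 8 of 12 endothelial and 3 of 8 smooth muscle, but these counts restate the rise and do not speak for its origin. Cells or RNA of the vessel wall in the intima sorts, whose gate of CD64, CD11c and MHC class II would remove single endothelial cells, thus cannot be told apart from expression by intima macrophages themselves, which was not tested. Single markers went both ways. Among the 8 endothelial markers above every adventitia library, Cdh5 was at 105 and 29.7 CPM and Egfl7 at 80.1 and 126 CPM in the intima. Kdr was at 0.235 and 0.0504 CPM in the intima and Myh11 at 0.470 and 0 CPM. The smooth muscle markers Cnn1, Actg2, Des and Synpo2, with too few reads for the test, were at 0 to 0.470 CPM there. Of the 14 endothelial genes, 6 were at 1 CPM or more in every adventitia library and 8 in both intima libraries. For the 12 smooth muscle genes these numbers were 1 and 5.

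The second pattern is the lower number of genes with a read in the intima. Depth runs against it, since the intima libraries were the deepest and at equal depth had at most 13220 genes, against at least 21012 in the adventitia. The gap was smaller for genes with 10 reads or more at equal depth. Their numbers were 8565 and 9592 in the intima and 10366, 10018 and 9990 in the adventitia. Few starting molecules may contribute. At equal depth 14.2% of the genes at 10 CPM or more in one intima library were under 0.5 CPM in the other. For a pair of adventitia libraries the share was at most 1.72%. A difference in cells between the intima pools could give the same, so this share cannot decide. A narrower program of gene expression or a purer population in the intima sort stays open and was not tested.

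The third pattern is the Apoe reads of the knockout-derived libraries, which amount to 0.355% of the intima level (95% interval 0.320 to 0.392), a share that reads exchanged between indexed libraries could leave of every abundant intima gene. Of 526 genes at 200 CPM or more in both intima libraries, 3 kept a share whose upper bound was below that of Apoe, namely Cav1 (0.214%), Cytl1 (0.225%) and Clu (0.253%), which met the bound of 3 genes set beforehand. That bound ignored the error of the Apoe share, below whose interval there was only 1 gene, Cytl1, and took the mean of the intima libraries, although either could supply the reads. Against the lower of the 2 intima ratios to Apoe reads, with the error of both counts, none of the other 525 genes was too low over the 3 adventitia libraries (Cav1 with 15 reads against 24.5, one-sided binomial p = 0.0313, and Cytl1 with 42 against 51.4, p = 0.119, both adjusted p = 1). In single libraries only Cav1 in adventitia replicate 2 was (1 read against 12.2, one-sided binomial adjusted p = 0.0482; Cytl1 in replicate 3 had 8 against 14.7, adjusted p = 1), so exchanged reads cannot be told apart from transcripts of the disrupted allele, which counts per gene do not resolve.

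A further hypothesis was that DNA of another strain, linked to the knockout allele, gives calls near Apoe. Within 10 Mb, 1 of 189 tested genes was called (0.529%), namely Apoc4, against 88 of 13218 elsewhere (0.666%), with a two-sided Fisher's exact p of 1. The share near Apoe was no higher, which met the bound set beforehand, but its 95% interval reaches 2.91%, so a moderate excess cannot be excluded and the hypothesis may still hold for Apoc4.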
